A study of Mus musculus with 14 samples.

How the data were processed

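RNA was measured in 14 libraries of differentiating mouse embryonic stem cells in 4 groups. There were 4 GLI1-induced and 4 control samples at D5, and 3 GLI1-induced and 3 control samples at D10. Groups were taken from the labels. Libraries were made from polyadenylated RNA and read from a single end, per the labels' protocols. The aligner, the counting, the statistical test and the genome build are not given in the sources used here.

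The files are the authors' own comparisons, with a full table and a table of selected genes for each day. Per the file headers, the authors gave for each Entrez gene a log fold change, an average log CPM, a p-value and an FDR. The log2 base of the average log CPM was checked here, as 2 raised to it sums to 1001540 at D5 and 1001340 at D10. The log fold change was taken to have the same base, which these sums do not test. The FDR deposited by the authors equals a Benjamini-Hochberg adjustment of the p-values, with largest differences of 2.72e-06 and 3.41e-05. The authors' selected genes are exactly those with an FDR under 0.05, which gives 671 at D5 and 13 at D10. Whether reads were counted with regard to strand is not given in the sources used here, so overlapping and antisense genes are uncertain. The full tables hold 15108 genes at D5 and 15744 at D10, and the filter behind them is not given in the sources used here. The depth per sample is unknown, and no value per library was used.

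Symbols came from the selected tables and, for the other genes, from an NCBI RefSeq gene table of assembly GRCm38.p6. It matched 94.6% of the Entrez identifiers on either day (14291 at D5 and 14891 at D10). No coordinates are printed, since the authors' build is not known. Genes that share reads with near-identical copies were looked for as rows with the same average log2 CPM (within 1e-05) and log2 fold change (within 0.001). There were 25 such repeated rows at D5 and 24 at D10.

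A signed z was computed from each p-value and the sign of the log2 fold change. An implied SE was derived as the size of the log2 fold change divided by the size of z. It is no replicate SD and inherits every assumption of the authors' test. Genes with an adjusted p under 0.05 are called changed. The difference between days was tested as the difference of the log2 fold changes over the root of the summed squares of the implied SEs, two-sided, with Benjamini-Hochberg adjustment over the 14792 genes in both tables. The libraries of the days are different samples, so the days share no control libraries. The test is approximate, since it uses a normal reference. Genes without a finite implied SE, 227 in the full D5 data and 288 at D10, were entered as no difference. Where z is very small the implied SE is unstable and can be too large. Genes that returned to no change at D10 can therefore be missed or ranked too low.

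Before the data were examined, 22 gene lists with 471 distinct genes, the tests, the alternatives and the rule for named genes were fixed. List members were matched by symbol. Lists with at least 5 measured members were tested with cameraPR of limma 3.58.1 on z, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a day. A correlation between genes could not be estimated, as that needs values per library. Gli1 is named first for each day. Named after it are the 10 largest rises and 10 largest falls among called genes with an average log2 CPM of at least 1, and up to 4 called members of each list with the smallest p. For the days, the 10 genes with the smallest p of the difference are named. Other genes were named after their values were seen: Ptch1, Gas1, Dcx, Elavl3, Slit1, Sulf1, Col22a1, Zic2, Gsx1, Nes, Nefm and Nefl at D10 or D5, and genes of small counts. So were Krt18, Gata4, Krt5, Tubb3, Dbx1, Dbx2, Olig3, Irx5, Pax6, Irx3 and Heyl at D10. Some genes that the rule takes are not reported here.

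Alternatives covered other thresholds on adjusted p (0.01 and 0.1), a 2-fold minimum, an average log2 CPM of at least 1, Holm's adjustment, a preset correlation of 0.05, ranks or log2 fold changes in the list test, and other choices of D5 genes. Added after seeing the data were a rescaling of z, counting repeated rows once, and leaving out genes of several lists. The rescaling divided z, within bins of about 500 genes ordered by average log2 CPM, by a factor that sets the median size of z to that of a standard normal. It assumes that most genes in a bin are unchanged.

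The procedures were tested on simulated data for the 14792 shared genes. Changes were drawn with the same SE that gave their p-values, and genes were independent. The low counts of unchanged genes and lists called therefore follow from the setting and do not measure error rates in the real data. In the simulated comparison of days, 82 of 100 genes changed by 1 on the log2 scale and 96 of 100 changed by 2 were called, with 8 of 14592 unchanged genes called. In the simulated D10 table with z shrunk by a factor of 0.5, rescaling returned a median factor of 0.501 and called 90 and 100 of 100 such genes and 7 unchanged ones. In simulated list tests, 2 of 2 changed lists and 0 of 20 unchanged lists were called. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.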

Results

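Polyadenylated RNA was sequenced from mouse embryonic stem cells that were being differentiated into neural cells in culture. The cells carried a GLI1 transgene in the A2Lox.cre background, a mouse line built for doxycycline-induced expression from a single landing site. GLI1 is a zinc-finger transcription factor that activates genes at the end of the Hedgehog pathway. Doxycycline at 500 ng/ml was given for 48 h, from day 3 to day 5 of differentiation. Libraries came from 4 induced and 4 untreated control samples at day 5 (D5), the neural progenitor stage. At day 10 (D10), the immature neuron stage and 5 days after washout, there were 3 induced and 3 control samples. The control cells received no doxycycline, so the drug and GLI1 changed together. The sources hold the comparison of induced with control samples on each day, with no values per library, so the depth per sample is unknown and the number of libraries that follow each direction cannot be given. The labels do not say whether the replicates were separate cultures. The authors' p-values concern only these samples, and how that test modelled the spread between them is not known. The p-values of the list tests compare genes, not samples.

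The first comparison asks which genes respond while GLI1 is induced, in cultures at the neural progenitor stage. Gli1 (Entrez 14632) was 27.8-fold higher in induced cells at D5 in the authors' deposited table, with a log2 fold change of 4.79, an adjusted p of 1.12e-81 and an implied standard error (SE) of 0.25 derived here. That value does not separate the transgene from the cell's own Gli1. Of 15108 genes in the authors' deposited table for D5, 671 changed at an adjusted p under 0.05, with 354 higher and 317 lower.

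In the authors' deposited table for D5, Sox18, a factor of blood and lymphatic vessel development, had the largest rise among genes with an average log2 CPM of at least 1, with a log2 fold change of 7.43 (adjusted p = 1.08e-118). The ventral neural tube factors Nkx2-9 and Nkx2-2 had log2 fold changes of 5.72 and 5.38 in the authors' deposited table. Hhip, a Hedgehog-binding membrane protein that dampens the signal, rose by 5.31 on the log2 scale in that authors' deposited table (implied SE 0.15). Hprt, a purine salvage enzyme whose locus holds the inducible cassette in A2Lox.cre cells, stood at 5.32 in the authors' deposited table. Also among the largest rises in the authors' deposited table were Cldn1 at 4.99, Hapln3 at 4.96, Gli1 and Ntng1 at 4.10.

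The largest falls at D5 were smaller in size than the largest rises. In the authors' deposited table for D5, Nwd2 had a log2 fold change of -2.60, the neuropeptide gene Sst -2.38 and Nxph4 -1.89. Nefm, a neurofilament subunit, was 3.05-fold lower in the authors' deposited table (log2 fold change -1.61, adjusted p = 5.12e-34, implied SE 0.13). The transcription factors Prdm12 at -1.56, Lhx1 at -1.50, Tfap2b at -1.49 and Prdm13 at -1.47 followed in the authors' deposited table, then Rgs4 at -1.45 and Pcdh10 at -1.44.

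Hedgehog target genes rose as a group at D5. Of the 21 measured members, 15 were higher in the authors' deposited table, 0 were lower and 6 did not pass, with a median log2 fold change of 1.39. Gli1, the induced gene, is among these 15, so that call was set by the experiment. It also counts in this list at D10 and in the comparison of days. The counts adjusted over the list alone were 15 higher and 1 lower. The list test gave an adjusted p of 1.42e-146. Besides Hhip and Nkx2-9, the member with the smallest p in the authors' deposited table was Hsd11b2 at 3.91, and the receptor Ptch1, which restrains the pathway, stood at 1.82. Among the 21 measured ligands, receptors and transducers of the pathway, 2 were higher and 3 lower in the authors' deposited table. These were the ligand Shh at 3.70 and Scube1 at 0.41 on the higher side, and the co-receptors Boc at -0.40, Cdon at -0.32 and Gas1 on the lower side. That list did not pass its test (adjusted p = 0.802).

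Regulators of ventral and of dorsal neural tube identity moved apart at D5. Of the 12 measured floor plate and ventral progenitor genes, 9 were higher and 0 lower in the authors' deposited table, and all 12 had a positive log2 fold change. The median was 1.63 and the list test's adjusted p was 2.31e-95. The count adjusted over the list alone was 10 higher. Nkx6-2 stood at 2.68 and Spon1, a secreted floor plate protein, at 1.84 in the authors' deposited table. Of the 20 measured dorsal and intermediate genes, 0 were higher and 5 lower in the authors' deposited table, with 19 below 0, a median of -0.39 and a list adjusted p of 2.64e-06. Adjusted over the list alone, 8 were lower. The roof plate and dorsal progenitor genes Zic1 at -1.15, Zic5 at -1.17, Zic2 at -0.56 and Pax3 at -1.12 led this group in the authors' deposited table, and Msx2 was the remaining call, which was lost with rescaled p.

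Markers of neurons fell at D5, and Notch pathway genes rose. Of the 38 measured neuron markers, 16 were lower and 1 higher in the authors' deposited table, and 21 did not pass. The median log2 fold change was -0.30 and the list test's adjusted p was 1.74e-07. With p adjusted over the list alone, 17 were lower and 4 higher. The lower genes in the authors' deposited table included Nefm, Nefl at -1.11 and the growth cone protein gene Gap43 at -0.70, and the single rise was Syt4 at 1.89. Dcx and Elavl3, expressed in most young neurons, stood at -0.0026 and 0.05 in the authors' deposited table and did not pass. Of the 19 measured Notch genes, 4 were higher and 0 lower in the authors' deposited table, with a list adjusted p of 6.15e-07. These were the effectors Heyl at 4.68, Hey2 at 1.18 and Hey1 at 0.94 and the glycosyltransferase Mfng at 0.64. Adjusted over the list alone, 7 Notch genes were higher.

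Progenitor, proneural and cell cycle genes showed no shift in a common direction at D5. In the authors' deposited table, 1 of 23 measured progenitor markers was higher (Slc1a3 at 1.11) and 2 were lower (Lhx2 at -0.93 and Ptn at -0.59). Of the 25 measured proneural and neurogenic genes, 3 were higher and 3 lower in the authors' deposited table, among them Neurog3 at 1.52 and Scrt2 at -1.24. Of the 30 measured S and G2/M phase genes, 0 passed in either direction in the authors' deposited table, and their median was -0.017. The list tests gave adjusted p values of 0.828, 0.802 and 0.802 for these groups.

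Markers of other lineages that the cultures could hold were lower or mixed at D5. Of the 23 measured pluripotency genes, 4 were lower and 0 higher in the authors' deposited table, namely Dppa5a at -0.73, Dnmt3b at -0.44, Lefty2 at -3.11 and Tdh at -0.83 (list adjusted p = 1.71e-05). Lefty2 and Tdh did not pass with rescaled p. Of the 12 measured surface ectoderm genes, 3 were lower and 0 higher in the authors' deposited table, namely the epithelial genes Esrp1 at -0.71, Cdh1 at -0.48 and Epcam at -0.58 (list adjusted p = 0.000716). With p adjusted over the list alone, 9 pluripotency and 4 surface ectoderm genes were lower. In the endoderm list, 2 of 17 measured genes were higher and 5 lower in the authors' deposited table. The higher pair, Foxa2 at 1.37 and Foxa1 at 1.41, are also floor plate factors, and Gata4 at -0.78 and Gata6 at -0.67 were among the lower genes in the authors' deposited table. The endoderm list did not pass (adjusted p = 0.118) and neither did the mesoderm and cardiac list (0.779). In the mesoderm and cardiac list, 3 of 15 measured genes were higher and 3 lower in the authors' deposited table. Foxf1 at 4.24 and T (brachyury) at 1.85 were among the higher genes, and Pdgfra at -0.81 and Gata4 among the lower. Endothelium and blood (0.0552), neural crest (0.759) and glia (0.853) also missed the threshold. Over the alternatives the adjusted p ran from 0.00274 to 0.268 for endoderm, from 4.52e-05 to 0.120 for endothelium and blood, which ranks turned downward, and from 0.00660 to 0.957 for mesoderm and cardiac genes, whose direction also turned. In the endothelium and blood list the mean was 0.60 with Sox18 in it, while the median was -0.47. The median of the mesoderm and cardiac list was -0.11 and its mean 0.30, and the glia, progenitor and ATF4 target lists also had a median, mean and test of mixed sign.

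The remaining lists held few calls at D5. Hox genes passed as a list in the lower direction (adjusted p = 0.0143), with 1 of 13 measured members lower in the authors' deposited table (Hoxa3 at -0.40). That call ended with a preset correlation of 0.05 (adjusted p = 0.0533). Targets of Wnt (adjusted p = 0.779), BMP (0.802), p53 (0.228) and ATF4 (0.802) and genes of the mitochondrial genome (0.0552) did not pass as lists. By ranks, p53 targets passed upward, and over the alternatives their adjusted p ran from 0.0102 to 0.575. That of mitochondrial genome genes ran from 0.000200 to 0.367. Among these lists, Bmp7 at 1.33, Lgr5 at 1.05, Lef1 at -0.89 and Vldlr at 0.86 changed in the authors' deposited table.

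**Figure D1:**
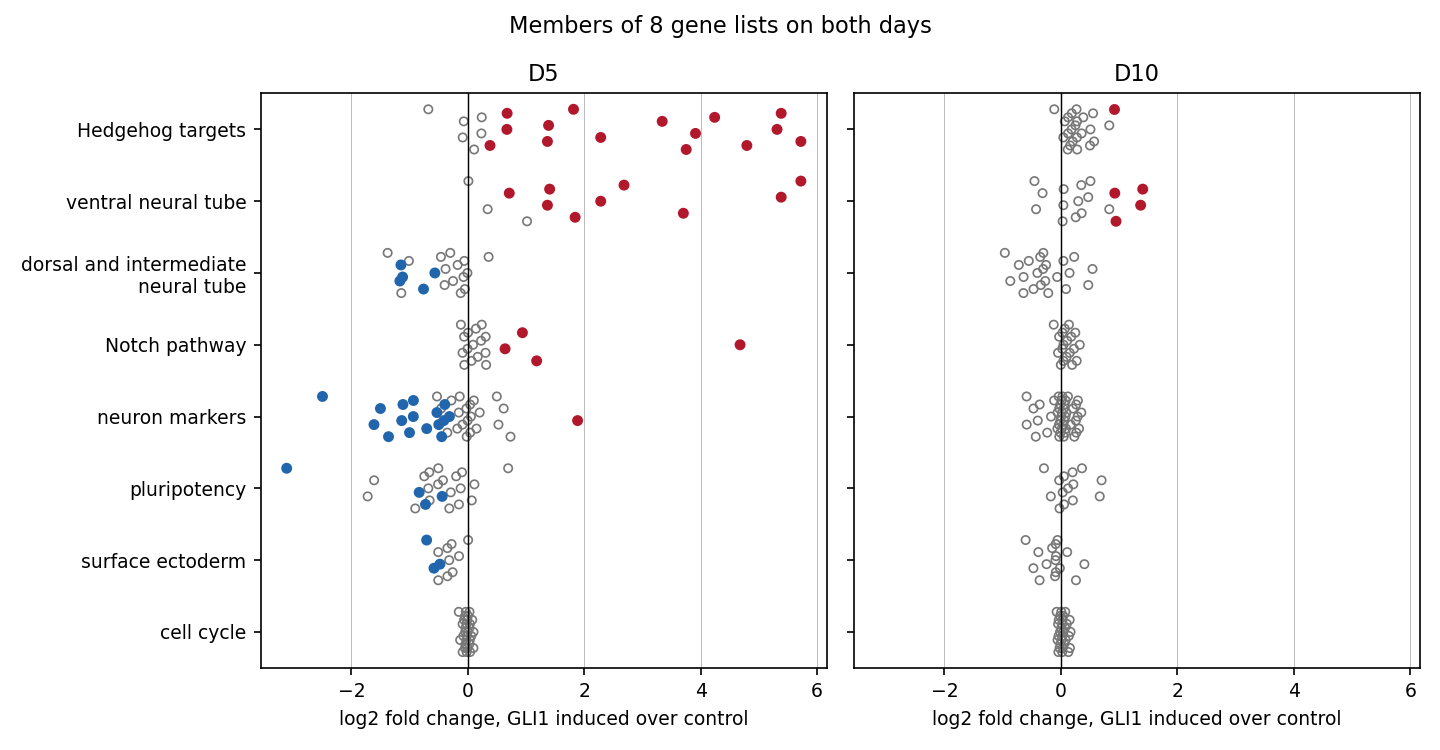
Log2 fold change of GLI1-induced over control cells (horizontal axis) for each measured member of 8 gene lists (rows), at D5 on the left and D10 on the right, from the authors' deposited table. Each point is a gene, filled red (higher) or blue (lower) where the adjusted p is under 0.05 and open otherwise. Among Hedgehog targets, 15 are filled at D5, with the induced Gli1 in that count, and 1 at D10.

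The second comparison asks what is left of the response 5 days after washout, in cultures at the immature neuron stage. These cultures did not hold transcripts of neurons alone. In the authors' deposited table for D10, the average log2 CPM was 9.04 for the keratin gene Krt18 and 7.48 for Gata4. It was 8.29 for the neuron gene Tubb3 and 9.11 for Dcx, while the keratin gene Krt5 was low at -0.06. Gli1 itself had a log2 fold change of 0.57 at D10 in the authors' deposited table and did not pass (adjusted p = 0.780, implied SE 0.18). Of 15744 genes in the authors' deposited table for D10, 13 changed at an adjusted p under 0.05, with 13 higher and 0 lower. At an unadjusted p under 0.05 there were 241 genes in the authors' deposited table for D10, 139 higher and 102 lower. After rescaling the p-values within bins of expression, an alternative chosen after seeing the data, 119 genes passed, 78 higher and 41 lower.

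Of the 13 genes higher at D10, 4 belong to the ventral neural tube list. Shh (Entrez 20423), the ligand made by the floor plate, was 2.65-fold higher in the authors' deposited table (log2 fold change 1.41, adjusted p = 3.21e-13, implied SE 0.17). The guidance molecules Slit2, Ntn1 and Slit1 stood at 0.98, 0.93 and 0.80 in the authors' deposited table. Spon1 stood at 0.95 and Sulf1, a heparan sulfate endosulfatase, at 0.86 in the authors' deposited table. Cavin2 stood at 1.36, the substance P receptor gene Tacr1 at 1.19, the vesicular glutamate transporter gene Slc17a8 at 1.17 and Thbs2 at 1.04 in the authors' deposited table. Igfbp3 at 0.92 and Col22a1 at 0.76 were also higher in the authors' deposited table. With Holm's adjustment 10 of the 13 genes passed, and Slc17a8 (0.183) and Col22a1 were among those that did not.

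Ventral regulators and Hedgehog targets were still shifted upward as groups at D10, by smaller amounts. Of the 17 measured ventral genes, 4 were higher and 0 lower in the authors' deposited table (among them Shh, Ntn1 and Spon1), with a median of 0.35 and a list adjusted p of 2.71e-26. Adjusted over the list alone, 6 were higher. Of the 23 measured Hedgehog targets, 1 was higher and 0 lower in the authors' deposited table (Igfbp3), but 22 had a positive log2 fold change, with a median of 0.27 and a list adjusted p of 1.67e-18. With p adjusted over the list alone, 5 Hedgehog targets were higher. The pathway component list passed upward (adjusted p = 0.00566) with Shh as its single call. Its adjusted p was 0.0555 with a preset correlation of 0.05, 0.325 by ranks and 0.424 without genes shared with other lists.

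Dorsal and intermediate genes were shifted downward as a list at D10 and progenitor markers upward, with no member of either list passing over all genes. Of the 22 measured dorsal and intermediate genes, 16 were below 0 in the authors' deposited table, with a median of -0.30 and a list adjusted p of 2.13e-10. The 6 above 0 were Dbx1 at 0.54, Dbx2 at 0.47, Olig3 at 0.23, Irx5 at 0.15, Pax6 at 0.09 and Irx3 at 0.04. Adjusted over the list alone, 6 were lower. Of the 24 measured progenitor markers, 20 were above 0 in the authors' deposited table, with a median of 0.18 and a list adjusted p of 6.36e-05. Examples in the authors' deposited table were Zic2 at -0.64 and Gsx1 at -0.87 among dorsal genes, and the intermediate filament gene Nes at 0.35 among progenitor markers. Of the 44 measured neuron markers, 0 passed in either direction in the authors' deposited table, with a median of 0.022, a mean of -0.0029 and a list adjusted p of 0.981. Among them, Nefm and Nefl stood at 0.06 and 0.026 in the authors' deposited table.

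Smaller shifts at D10 passed the list test and depended on the preset correlation between genes and on other settings. Notch (adjusted p = 0.00993) and proneural genes (0.0391) leaned upward, and endoderm (0.0117), surface ectoderm (0.0313) and neural crest markers (0.0366) leaned downward, with 0 members of these lists called over all genes. With a preset correlation of 0.05 in place of 0.01, 4 of the 10 lists that passed at D10 still did, and the adjusted p of these 5 lists that leaned up or down ran from 0.0660 to 0.154. Each of them also missed the threshold in at least 1 other alternative, with an adjusted p of up to 0.0663 for Notch, 0.238 for proneural genes, 0.0753 for endoderm, 0.0521 for surface ectoderm and 0.165 for neural crest. Pluripotency (adjusted p = 0.0545), ATF4 targets (0.0545), Hox (0.128), cell cycle (0.223), Wnt (0.420), glia (0.431), p53 (0.431), mitochondrial genome (0.443), mesoderm and cardiac (0.584), BMP (0.596) and endothelium and blood (0.696) lists did not pass. Of these 11, the first 3 passed in some alternatives: over them the adjusted p ran from 0.0156 to 0.154 for pluripotency genes, from 0.0228 to 0.231 for ATF4 targets and from 0.0478 to 0.461 for Hox genes.

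The third comparison asks whether the response differed between the days. Of 14792 genes in both of the authors' deposited tables, 183 had a log2 fold change that differed between D5 and D10 in the test computed here from the implied SEs. In 179 of them the value was closer to 0 at D10, and 179 had passed at D5. The smallest p belonged to Hhip, which went from 5.31 at D5 to 0.55 at D10 in the authors' deposited table (adjusted p of the difference 2.12e-87). Cldn1 went from 4.99 to -0.31 and Ntng1 from 4.10 to 0.016 in the authors' deposited table. Vtn, Gli1, Nkx2-9, Hsd11b2, Frem1, Cxcl12 and Tmtc1 complete the 10 genes with the smallest p, each closer to 0 at D10.

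The other 4 genes that differed were further from 0 at D10, and are named here because there were few of them. Thbs2 went from -0.42 to 1.04 in the authors' deposited table (adjusted p of the difference 0.00128). Tenm4, a teneurin of synapse formation, went from -0.36 to 0.50 (0.00283), Mmp2 from -0.21 to 0.58 (0.0281) and Sulf1 from 0.26 to 0.86 (0.0356) in the authors' deposited table. Shh, Spon1 and Col22a1, which passed on both days, had smaller values at D10 (adjusted p of the difference 2.14e-08, 0.000109 and 2.44e-10). For Slit2, which was 0.88 at D5 and 0.98 at D10 in the authors' deposited table, the difference was 0.10 and did not pass.

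The genes changed at D5 were then followed to D10. Of the 671 genes changed at D5, 642 were in the D10 table, and 455 of them (70.9%, exact 95% binomial interval 67.2% to 74.4%) had the same sign on both days in the authors' deposited table. Genes are not independent, so this interval is too narrow. Among the 14150 genes that had not passed at D5, the share with the same sign was 58.1%. For the 223 D5 genes with at least a 2-fold change it was 61.9%, with an interval of 55.2% to 68.3% that includes that share. The 335 higher genes had a median of 0.99 at D5 and 0.07 at D10 in the authors' deposited table, and the 307 lower genes had medians of -0.66 and -0.08. Among the genes in both tables, 6 were higher on both days at an adjusted p under 0.05, where 0.204 would be expected for independent lists of 335 and 9 genes. These were Shh, Slit2, Ntn1, Spon1, Slit1 and Col22a1. Across the 14792 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.166 and Spearman's rho was 0.210. Over the 642 genes alone, r was 0.332.

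**Figure D2:**
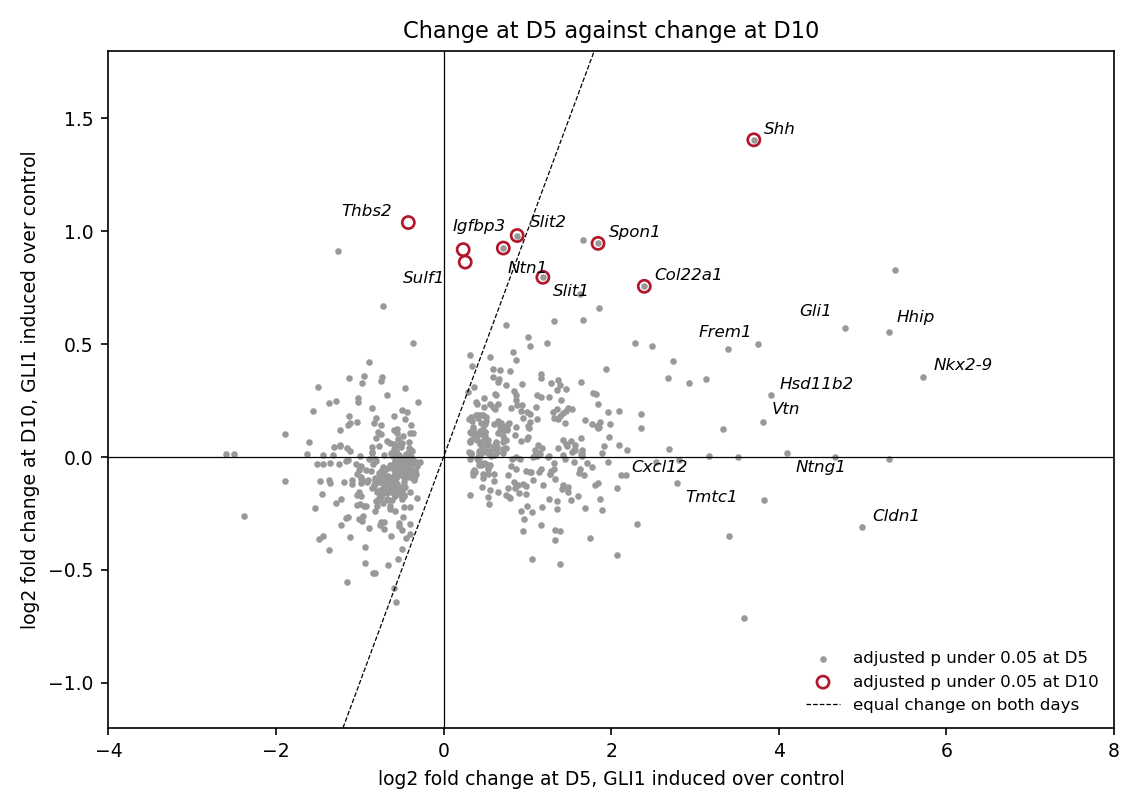
Log2 fold change of GLI1-induced over control cells at D5 (horizontal axis) against that at D10 (vertical axis), from the authors' deposited table, for the 642 genes with an adjusted p under 0.05 at D5 and the genes called at D10 that are in both tables. Grey points are genes called at D5 and red circles genes called at D10; most points lie near 0 on the D10 axis, away from the dashed line of equal change, and Shh is the highest at D10.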

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

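Among the tests given in this part, the rescaling of z was added after seeing the data, and the slope of D10 on D5 values was chosen after its result was seen.

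The change at D10 differed from that at D5 for 183 genes, by a test of the difference itself. For the 10 with the smallest p, the D10 minus D5 difference of log2 fold changes was -4.76 for Hhip, -3.66 for Vtn, -4.22 for Gli1, -5.37 for Nkx2-9, -3.64 for Hsd11b2, -5.30 for Cldn1, -2.92 for Frem1, -2.66 for Cxcl12, -4.09 for Ntng1 and -2.90 for Tmtc1. Single samples were not examined for standing apart, since no values per library were used.

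Few genes passed at D10, 13 against 671 at D5. The values argue against larger errors at D10 as the whole cause. Of the 642 D5 genes, 363 (56.5%) would have passed at D10 with their D5 change and the implied SE typical of their expression there. Only 6 did. These genes were selected for passing at D5, which can enlarge their D5 change, so the 56.5% may be too high. A conservative test at D10 may account for part of the low count at D10. The median of z squared was 0.364 of the value for unchanged genes, and 119 genes passed once z was rescaled within bins of expression. A fading of the response after washout is also consistent with the values, since the slope of D10 on D5 log2 fold changes was 0.0443 (bootstrap 95% interval 0.0197 to 0.0685) over the 223 genes called at D5 with at least a 2-fold change. Both stay open together, as hypotheses, and the maturing of the cells between the days was not separated from washout.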

How the results depend on the processing

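No paired analysis was possible because the tables hold comparisons of groups and no values per library. For the same reason, leaving out replicates, refits from counts, other splits of the samples and an SE from the authors' test statistic were not run, and the depth behind each gene cannot be weighed. Of 671 genes at D5, 433 passed at an adjusted p under 0.01, 250 with at least a 2-fold change too (182 higher, 68 lower) and 242 with Holm's adjustment (180 higher, 62 lower). These criteria are stricter by construction. At D10, 6 of 13 had at least a 2-fold change. With p rescaled within expression bins, chosen after seeing the data, 119 genes passed at D10 (78 higher, 41 lower, 65.5% higher against 100%) and 361 differed between days, since that rescaling raises z where it was small. The other alternatives gave 579 to 803 genes at D5, 10 to 14 at D10 and 162 to 222 between days. The same-sign share was 61.9% (interval 55.2% to 68.3%) for D5 genes with at least a 2-fold change, and r across genes was 0.221 with an average log2 CPM of at least 1 and 0.332 among D5 genes; the cause was not tested. With a preset correlation of 0.05, which widens the null by construction, 4 lists passed at D10 in place of 10. No list that passed changed direction. For named genes the direction could not change, since every alternative kept the authors' log2 fold changes. At D5, 119 of 131 list results and 168 of 197 results over the 68 genes that the naming rule takes kept their side of the threshold, and at D10 111 of 132 and 30 of 33 did. The D5 genes lost were lost with Holm's adjustment, and Lefty2 (0.0808), Tdh (0.201), Msx2 (0.0892) and Lmo2 (0.0680) with rescaled p too.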

Other observations

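The lists on the difference between days, the scan of gene families, the rescaled D10 genes and the tests on Hprt and on neuron markers were chosen after the data were seen.

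Neuron markers were lower at D5 and not at D10, and the list test on the difference between days passed for them. Over the 38 markers in both of the authors' deposited tables the median log2 fold change went from -0.30 to 0.03 (adjusted p = 6.21e-09), and 9 of the genes differed singly. Pluripotency genes went from a median of -0.37 to 0.09 (adjusted p = 1.74e-05). Dorsal and intermediate genes went from -0.39 to -0.29 (adjusted p = 0.00288), ventral genes from 1.63 to 0.35 (6.18e-61) and Hedgehog targets from 1.38 to 0.24 (1.16e-105). In all, 7 of 22 lists passed, with surface ectoderm and endothelium and blood as the others. The Notch list (adjusted p = 0.114) did not. That result cannot decide whether the Notch rise faded. Heyl, at 4.68 at D5 and -0.0011 at D10, had no finite implied SE at D10 and was entered as no difference.

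Gene families defined by a shared prefix of the RefSeq symbol, which differs from the authors' symbol for some genes, were scanned at D5, with 448 families and 896 tests of called genes in each direction by Fisher's exact test. The 2 that passed were both higher. All 6 measured Nkx homeobox genes rose, where 0.144 would be expected (adjusted p = 1.67e-07). Of 15 measured Pramel genes, a clustered multicopy family, 7 were called higher where 0.361 would be expected (adjusted p = 1.08e-05). The Pramel values are uncertain: these genes have an average log2 CPM under 0, 3 of the 7 did not pass with rescaled p, 2 of the 7 repeat another gene's values to within 1e-05 in log2 CPM, and reads shared between copies can make one change count several times.

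The D10 genes that passed with rescaled p included 78 higher and 41 lower genes, while 0 were lower with the authors' p-values. Of the dorsal and intermediate list, 5 members were lower and 1 higher with rescaled p. In the authors' deposited table for D10, Barhl1 stood at -1.21, Gsx1 at -0.87, Msx3 at -0.72, Pou4f2 at -0.67, Zic2 at -0.64, Wnt1 at -0.64 and Zic1 at -0.55. Calb2 stood at -0.65 in the authors' deposited table and was the gene nearest to passing on the lower side (adjusted p = 0.0959). On the higher side, Gata2 at 0.65, Dbx1 at 0.54 and Tal1 at 0.47, and the Hedgehog targets Gli1 at 0.57, Hhip at 0.55, Ccnd1 at 0.38 and Ptch1 at 0.28, passed with rescaled p, with values from the authors' deposited table for D10. These genes were chosen after their values were seen, and no theme was tested among them.

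The implied SE depended mostly on expression. Among genes with a size of z between 1 and 4, 86.4% at D5 and 87.1% at D10 had an implied SE within 20% of the running median at their average log2 CPM. The ratio of the median z squared to its value for unchanged genes fell from 1.49 for D5 genes with an average log2 CPM of 0 to 2 down to 0.300 above 8, and from 0.657 to 0.186 at D10.

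Hprt was 40.0-fold higher at D5 in the authors' deposited table. Transcription from the doxycycline-induced cassette at this locus is a candidate explanation. It needs the rise to end with washout, and Hprt stood at -0.0092 at D10 in the authors' deposited table (implied SE 0.49), while its nearest measured neighbours Phf6 at 0.17 and C430049B03Rik at 0.15 did not pass at D5. Whether Hprt instead responded to GLI1 like Hedgehog targets was not settled. The median of the targets called at D5 was 0.318 at D10. The implied SE of Hprt cannot judge that gap, because its z was very small and such an SE is unstable. For D10 genes with an average log2 CPM of 2 to 4, the median implied SE was 0.195, which is below 0.318. That SE is not the one of Hprt, and the comparison rests on a single gene, so no conclusion is drawn.

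Neuron markers fell at D5, and the values argue against dilution by cells of 7 other lineages as the whole cause. Of 95 measured markers of these lineages 18 were lower and 7 higher. The ventral neural tube list, with 9 of 12 measured genes higher, was not among them. Dilution by floor plate or ventral progenitor cells was therefore not tested. The pan-neuronal genes did not fall by a common amount, as Cochran's Q test over the 21 members other than Syt4 gave a p of 2.21e-40. Syt4 was left out after its rise was seen, and the test rests on the implied SEs. It cannot decide on fewer neurons, because members need not draw the same share of their reads from the neurons lost. Stress from doxycycline cannot be told apart from GLI1, because controls lacked the drug, and the ATF4 target list (adjusted p = 0.802) excludes nothing. Transcripts of the mitochondrial genome, whose translation doxycycline can inhibit, had an adjusted p of 0.0552 in the upward direction at D5, which ran from 0.000200 with rescaled p to 0.367 with log2 fold changes in place of z. An effect of GLI1 on neurons other than their number was not tested; 9 of 22 pan-neuronal and 7 of 16 subtype and other markers were lower.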
